A study of Danio rerio with 12 samples.

How the data were processed

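Total RNA from adult F3 zebrafish brains was sequenced as TruSeq paired-end libraries of 100 bp reads, per the labels' protocols. Series labels list 12 samples, 6 of each lineage, as biological replicates, and do not say whether a sample is 1 brain or several. The submitters' processing notes name CASAVA 1.8.2, cutadapt, FastQC, TopHat, Cuffnorm and the genome build Zv9, with no settings. Library strand, annotation version and the treatment of reads shared between gene copies are not given in the sources used here, so values of duplicated genes carry that uncertainty. No genome was used and no coordinates are printed.

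The authors deposited 2 tables of 32674 genes. One is a table of signal values, which are fragment counts per gene that the authors had divided by 1 size factor per library. This was read from the values, because 98.2% to 98.9% of positive values under 200 steps were whole multiples of a step particular to the library, within 0.01. The other holds FPKM values deposited by the authors, fragment counts normalised for gene length and sequencing depth and scaled across libraries. Each table has 1 column with no name in the header, which was not used in any step, which left 5 control and 6 MeHg libraries. The division by size factors removes differences in depth that affect all genes alike, and a low value in a shallow library rests on few fragments. The implied depth of 2062480 to 7503930 fragments follows from the step and is a reading of the values. A value of 3 implied fragments corresponds to a scaled count of 6.86 in the shallowest library (control replicate 2) and 2.01 in the deepest (MeHg replicate 5).

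Gene symbols came from the tables for 20495 genes and through Ensembl identifiers from a reference table of names for 1553 more, while 10626 genes kept the identifier. Of all identifiers, 21027 were in the reference table.

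Scaled counts were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust estimation, statmod 1.5.0), lineage as the factor and no covariate. Genes with a value of at least 10 in at least 6 libraries were kept, 16364 in all, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Lineages, tests, gene lists and the naming rule were chosen before the data were examined. That plan assumed 12 libraries, and the same tests were run on 11. It also held tests of raw counts as alternatives, which were left out because the values are not raw counts. Named genes are up to 12 higher and 12 lower genes past the threshold with a gene symbol and the largest absolute log2 fold change, up to 3 members of each list with the smallest p, and the 3 most abundant members of a list for libraries that stand apart. Clone-style names were left out.

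Of 31 gene lists, 27 had at least 3 tested members. Those for lens, pituitary, liver and plasma proteins, and germ cells had 1, 1, 1 and 2 and were not tested. Lists were tested with camera in limma (inter-gene correlation 0.01), camera with an estimated correlation, and fry. A score per library was the mean log2 value of a list's members, each gene centred over the libraries. Differences of scores and of library measures between lineages were tested over all 462 splits with an exact two-sided permutation test, whose smallest p is 0.0022. The lists cover brain cell types and signalling, tissues next to the brain, stress responses, the clock, epigenetic regulators, and core cellular machinery.

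The gene test was tried on simulated data for the MeHg lineage against the control lineage with 200 changed genes. Of 16551 genes in that fit, 47% of genes changed 2-fold and 84% of genes changed 4-fold were recovered, all with the right sign, with 11 false calls (7.75% of calls). A simulation with no change gave 0 calls. Many changes of 2-fold or less would therefore be missed with 5 and 6 libraries. Each gene was simulated independently, with no effect shared by the genes of a library, so the false call rates may not carry over. Changed genes were drawn only from those with a mean well above the filter's minimum, so recovery near that minimum was not measured.

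Alternatives covered other scalings, voom with sample quality weights on rounded values, filters, pseudocounts of 0.5 and 5, the FPKM table (pseudocounts 0.1 and 1), thresholds, the replicate number as a block, each library left out in turn, and other list tests. Library totals as scaling, array weights, a residual principal component, list scores as covariates and 2 sets of omitted libraries were added after seeing the data. Total scaled count, FPKM total, implied depth, mitochondrial share, share of the 10 most abundant genes and genes above 0 did not differ between lineages beyond the spread, with exact permutation p from 0.364 to 0.807. Mitochondrial genes took 8.04% ± 3.40 of control values (SD, n = 5) and 7.53% ± 0.88 of MeHg values (SD, n = 6). Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and plotted with matplotlib 3.10.9.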

Results

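The data set asks whether ancestral exposure of zebrafish (Danio rerio) to methylmercury is followed by a different brain transcriptome in descendants that never met the compound. Methylmercury is an organic form of mercury that enters the brain. Eggs of the EK strain were held for 24 h in 0 or 0.03 µM methylmercury, with ethanol as the vehicle, and founded a control lineage and a methylmercury (MeHg) lineage. RNA was sequenced from adult brains of the F3 generation of each lineage, with no further exposure. The labels describe 6 biological replicates per lineage. Measurements of 5 control libraries (replicates 2, 4, 5, 6 and 8) and 6 MeHg libraries (replicates 1, 2, 4, 5, 7 and 8) were compared. Each value below is a fragment count that the authors had divided by a size factor per library, called the scaled count here. The most common low positive value in a library was taken as 1 fragment. This gave an implied depth of 2062480 to 6100930 counted fragments in control libraries and 3248620 to 7503930 in MeHg libraries, a difference within the spread between libraries (exact permutation test, two-sided p = 0.630).

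The clearest difference between the lineages lay in genes of the circadian clock, the transcriptional feedback loop that runs with a daily period. Messages of the period genes per1a, per1b and per3 and of the Rev-erb genes nr1d1 and nr1d2b were lower in MeHg-lineage brains, and those of the Bmal genes arntl1a and arntl2 and of clocka were higher. No sample label gives a collection time, so lineage and hour of sampling cannot be told apart for these genes. Of 16364 genes tested, 44 passed a limma adjusted p of 0.05, 16 higher and 28 lower in the MeHg lineage, with fold differences of 1.78 to 11.2. The median log2 fold change of all tested genes was 0.03, and 1082 genes had an unadjusted p under 0.05. In each of the 44 genes the 6 MeHg libraries did not overlap the 5 control libraries. Such separation was seen in 224 of all tested genes, or 1.37%, where chance gives 0.433%. Leaving out control replicate 5 raised the number of genes past the threshold from 44 to 72. Without any scaling between libraries 24 genes passed, 12 higher and 12 lower. That setting undid the authors' size factors, so differences in depth between libraries stayed in its values. All fold changes are on the log2 scale of the scaled count plus 1, which understates changes of weakly expressed genes. They compare means of log2 values. A fold can therefore differ from the ratio of the mean scaled counts printed beside it, as for per3.

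**Figure D1:**
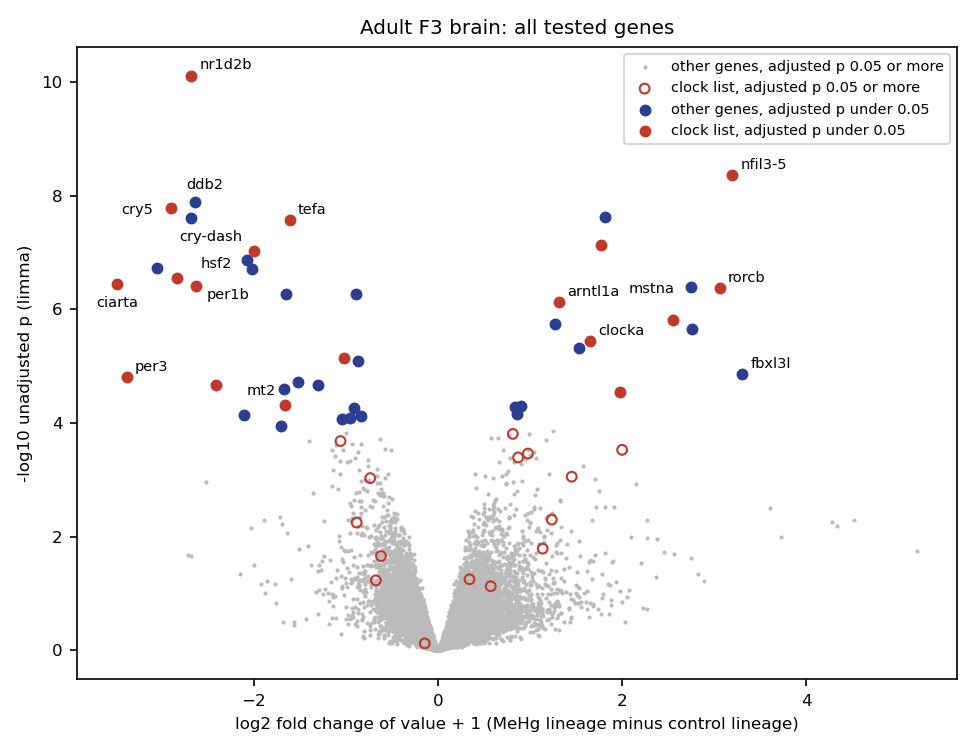
Log2 fold change (MeHg lineage minus control lineage, x axis) against the -log10 unadjusted limma p (y axis) for the 16364 tested genes. Red points belong to the clock list, filled where the adjusted p was under 0.05 (18 genes), and blue points are the 26 other genes under that threshold.

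Among 33 tested members of a clock gene list fixed in advance, 7 were higher, 11 were lower and the remaining members did not pass the threshold over all genes. Adjusted over the list alone, 14 were higher and 15 lower. By chance 0.089 members would be expected among 44 genes (Fisher's exact test, two-sided p = 9.529e-40). That test treats genes as independent draws, while clock genes act in 1 loop and were measured in the same libraries. Its p therefore does not measure the spread between libraries. Because members went both ways, the list did not move as a whole in one direction. Its median log2 fold change was -0.14, the camera adjusted p was 0.292 (limma; 0.903 with an estimated correlation), and fry for changes in either direction gave an adjusted p of 4.19e-08.

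Lower members included the period genes per1a, per1b and per3. Period proteins repress the Clock and Bmal activators. The period gene per2 did not pass, at a log2 fold change of -0.62 ± 0.24 (SE, limma adjusted p = 0.643). The scaled count of per1b (ENSDARG00000012499) was 1054 ± 259 in control brains (SD, n = 5) and 179 ± 74.0 in MeHg-lineage brains (SD, n = 6), a log2 fold change of -2.62 ± 0.27 (SE, limma adjusted p = 0.00040). For per1a (ENSDARG00000056885) the log2 fold change was -2.83 ± 0.29 (SE, limma adjusted p = 0.00035). The largest relative losses were in ciarta (ENSDARG00000058094), a circadian repressor of transcription, and per3 (ENSDARG00000010519). The former fell 11.2-fold, from 225 ± 95.6 to 18.8 ± 8.54. The latter fell 10.4-fold, from 644 ± 352 to 47.7 ± 8.57 (limma adjusted p = 0.0088), although control replicate 5 held only 89.9, far from the 614 to 1036 of the other control libraries. Without that library the fall of per3 was 16.0-fold (limma adjusted p = 1.46e-07). Rev-erb nuclear receptors repress Bmal transcription. The Rev-erb gene nr1d2b (ENSDARG00000009594) had the smallest p of any gene, at 2371 ± 371 in control brains (SD, n = 5) and 368 ± 50.1 in MeHg-lineage brains (SD, n = 6), a log2 fold change of -2.68 ± 0.14 (SE, limma adjusted p = 1.27e-06). Its relative nr1d1 (ENSDARG00000033160) fell from 450 ± 230 to 83.4 ± 33.1 (limma adjusted p = 0.0108).

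Higher members included genes of the activators. The Bmal gene arntl1a (ENSDARG00000006791) rose from 182 ± 41.6 (SD, n = 5) to 446 ± 37.4 (SD, n = 6), a log2 fold change of 1.32 ± 0.15 (SE, limma adjusted p = 0.00061), and clocka (ENSDARG00000011703) from 97.9 ± 25.4 to 309 ± 81.6 (limma adjusted p = 0.0025). The second Bmal gene, arntl2 (ENSDARG00000041381), had a log2 fold change of 1.98 ± 0.31 (SE, limma adjusted p = 0.0136; 0.0506 without MeHg replicate 7). Their relatives arntl1b and clockb did not pass, at 1.45 ± 0.34 and 0.57 ± 0.30 (SE, limma adjusted p = 0.148 and 0.810). Larger rises were measured for nfil3-5 (ENSDARG00000094965), a bZIP repressor that competes with activators at D-box elements, and rorcb (ENSDARG00000017780), a nuclear receptor of the ROR family that activates Bmal genes. The first rose 9.16-fold, from 175 ± 52.3 to 1581 ± 348 (limma adjusted p = 3.6e-05), and the second 8.34-fold, from 14.2 ± 6.13 to 114 ± 14.3 (limma adjusted p = 0.00040). The cryptochrome gene cry2b (ENSDARG00000091131) rose from 371 ± 44.2 to 1296 ± 323, with a log2 fold change of 1.78 ± 0.16 (SE, limma adjusted p = 0.00015). The nuclear receptor gene nr1d4b (ENSDARG00000059370) rose from 29.9 ± 8.82 to 190 ± 92.7, the opposite direction to nr1d1 and nr1d2b.

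**Figure D2:**
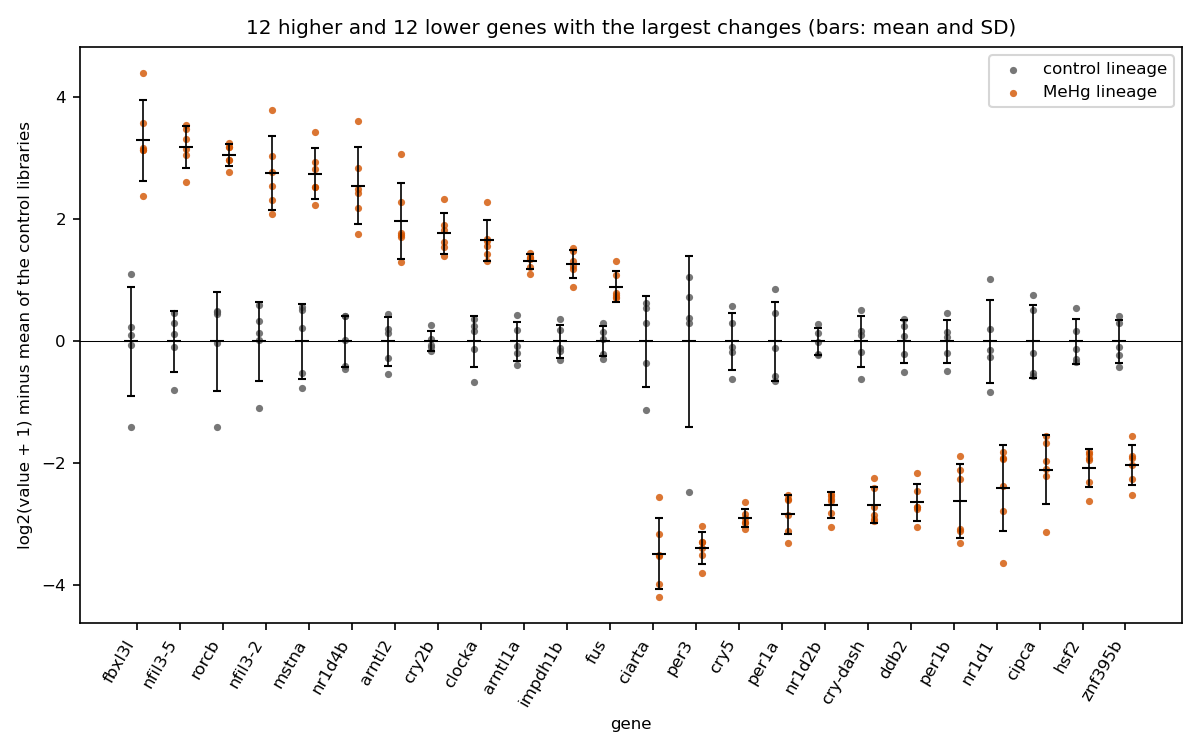
Log2(scaled count + 1) of the 12 higher and 12 lower genes named by the rule fixed in advance, per library, minus the control mean of the gene (y axis), with genes on the x axis. Grey points are the 5 control libraries, orange points the 6 MeHg libraries, and bars give the mean and SD. In each gene the orange points lie on one side of the grey points, and the lowest grey point of per3 is control replicate 5.

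Other lower genes have known roles in the response of cells to light. The photolyase-family genes cry5 (ENSDARG00000019498) and cry-dash (ENSDARG00000002396) fell 7.44-fold and 6.39-fold. The first, a member of the clock list, went from 116 ± 36.9 in control brains (SD, n = 5) to 14.1 ± 1.63 in MeHg-lineage brains (SD, n = 6; limma adjusted p = 6.3e-05), and the second from 205 ± 58.2 to 30.8 ± 6.77 (limma adjusted p = 6.3e-05). The gene ddb2 (ENSDARG00000041140), whose product recognises ultraviolet lesions, fell from 212 ± 49.5 to 33.0 ± 7.35 (limma adjusted p = 6.3e-05). The grouping of these genes was made after their values were seen.

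Outside the clock list, 26 genes passed the threshold. The F-box gene fbxl3l (ENSDARG00000037738), related to the gene whose product marks cryptochromes for degradation, had 8 implied fragments in all control libraries together and 141 in the MeHg libraries. Scaled for depth this is a ratio of 12.8 (95% interval 6.31 to 30.2, counting error only; limma adjusted p = 0.0081). The bZIP gene nfil3-2 (ENSDARG00000043237) rose 6.79-fold, from 34.9 ± 13.0 (SD, n = 5) to 245 ± 117 (SD, n = 6; limma adjusted p = 0.0016). A gene for a Clock-interacting repressor, cipca (ENSDARG00000075397), fell from 40.3 ± 17.6 to 8.47 ± 3.07 (limma adjusted p = 0.0298), but its adjusted p was 0.0518 to 0.110 without any 1 of control replicates 2, 4 and 6 and MeHg replicates 1, 2, 5 and 7. The myostatin gene mstna (ENSDARG00000042947), a growth inhibitor of the TGF-beta family, rose 6.73-fold, from 26.2 ± 10.4 to 177 ± 54.9 (limma adjusted p = 0.00040). The guanine nucleotide synthesis gene impdh1b (ENSDARG00000029524) rose from 172 ± 33.5 to 416 ± 64.6 (limma adjusted p = 0.0013). The heat shock factor gene hsf2 (ENSDARG00000053097) fell from 391 ± 107 to 91.3 ± 18.4 (limma adjusted p = 0.00022), and the zinc finger gene znf395b (ENSDARG00000024195) from 349 ± 87.1 to 85.0 ± 19.3 (limma adjusted p = 0.00026). The RNA-binding protein gene fus (ENSDARG00000037968) rose from 429 ± 72.8 to 802 ± 148 (limma adjusted p = 0.0230), with an adjusted p of 0.0625 to 0.0793 without any 1 of control replicates 2, 4 and 6 and MeHg replicate 7. Another gene, amd1 (ENSDARG00000043856), which acts in polyamine synthesis, was singled out after its values were seen because its libraries varied little, and fell from 2317 ± 133 to 1253 ± 82.5 (limma adjusted p = 0.00047). Without scaling between libraries, per3, arntl1a, impdh1b, fus, cipca and amd1 did not pass, at log2 fold changes of -3.09 ± 0.60, 1.60 ± 0.41, 1.56 ± 0.41, 1.18 ± 0.41, -1.81 ± 0.56 and -0.60 ± 0.41 (SE). In the 7 libraries without high epidermis or muscle scores, nr1d1, nr1d4b and arntl2 did not pass, at -2.48 ± 0.58, 2.44 ± 0.41 and 1.98 ± 0.39 (SE), against -2.41 ± 0.37, 2.56 ± 0.30 and 1.98 ± 0.31 in all libraries.

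Of 23 tested genes of the metal and oxidative stress list, 1 passed the threshold, over all genes and adjusted over the list alone. It was the metallothionein gene mt2 (ENSDARG00000041623), whose product binds zinc, copper and mercury. It fell 3.18-fold, from 942 ± 279 in control brains (SD, n = 5) to 300 ± 113 in MeHg-lineage brains (SD, n = 6), a log2 fold change of -1.67 ± 0.26 (SE, limma adjusted p = 0.0126), and did not pass without scaling (-1.38 ± 0.40) or in those 7 libraries (-1.54 ± 0.32). The antioxidant regulator keap1a had a log2 fold change of -0.59 ± 0.21 and the superoxide dismutase gene sod2 of -0.45 ± 0.18, with limma adjusted p of 0.547 and 0.661. No member of the 18 tested selenoprotein genes passed. The first by p was sepn1, at 0.57 ± 0.18 (limma adjusted p = 0.478).

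Chaperone genes of the heat shock and unfolded protein list had negative values in 16 of 23 members (9 of 23 without scaling). None passed over all genes, and 5 were lower when adjusted over the list alone. The mitochondrial chaperonin gene hspe1 had a log2 fold change of -0.93 ± 0.18, hsp90aa1.2 of -0.95 ± 0.20 and the constitutive hspa8 of -0.65 ± 0.16, with limma adjusted p over all genes of 0.0682, 0.0990 and 0.221. Leaving out control replicate 5, or MeHg replicate 1, 5 or 7, left 3 genes past that list's own threshold. Without control replicate 5, hspe1 also passed over all genes (limma adjusted p = 0.0242). Immediate early genes, which respond to neuronal activity, had positive changes in 19 of 21 members, with 8 at an unadjusted p under 0.05. One of them, npas4a, passed adjusted over the list alone, at 851 ± 410 against 1918 ± 485 (log2 fold change 1.33 ± 0.35, limma adjusted p = 0.265 over all genes). That count of 1 became 0 without any 1 of MeHg replicates 1, 2, 4, 5 and 7, 2 without control replicate 4 or MeHg replicate 8, and 7 without control replicate 8. As scores per library, the heat shock list was lower by 0.33 (exact permutation test, two-sided p = 0.0043, adjusted p = 0.117 over 27 lists) and the immediate early list higher by 0.57 (exact p = 0.0195, adjusted p = 0.175). A list of epigenetic regulators was higher by 0.23 (exact p = 0.0152, adjusted p = 0.175), with no member past the threshold. Without control replicate 5 that difference was 0.090 (exact p = 0.0524).

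Of the 27 lists with at least 3 tested members, 10 passed camera's threshold. With a correlation estimated for each list, 0 passed, with a smallest adjusted p of 0.748, and 0 passed fry in one direction or the exact test of the scores, where 3 had an unadjusted p under 0.05. The lists with positive camera calls were immediate early, retina and pineal, cholesterol synthesis and epigenetic regulators. Those with negative calls were nuclear genes of oxidative phosphorylation, ribosomal proteins, heat shock, neuropeptide and stress hormone genes, proteasome, and metal and oxidative stress. All 74 ribosomal protein genes had negative values, with a median of -0.30, and 72 of 77 oxidative phosphorylation genes, with a median of -0.25. Without scaling, which moved the median of all genes from 0.03 to 0.30, negative values numbered 46 and 30. Without control replicate 5 they numbered 69 and 57, with medians of -0.13 and -0.12, and the differences in score shrank from -0.29 to -0.12 and from -0.23 to -0.064. The ribosomal median was -0.20 without MeHg replicate 8, and that of oxidative phosphorylation -0.38 without control replicate 4. No gene in either list passed over all genes, and the camera adjusted p with an estimated correlation was 0.749 for both lists. Adjusted over the list alone, 34 oxidative phosphorylation genes were lower without control replicate 4 and 0 with all libraries. Control replicate 5 had the highest score of any library for both lists, and without it the camera calls of the proteasome (adjusted p = 0.926), metal and oxidative stress (0.403), neuropeptide (0.0801) and epigenetic (0.0639) lists ended. The retina and pineal call ended without MeHg replicate 8 (0.202) or control replicate 4 (0.0711), and the cholesterol call without control replicate 8 (0.112), control replicate 4 (0.0711) or MeHg replicate 1 (0.0614). The epigenetic call also ended without control replicate 4 or 8 or MeHg replicate 1 or 7. Neuropeptide genes included agrp, an appetite peptide, at 42.6 ± 34.8 against 11.2 ± 6.09 (limma adjusted p = 0.366). Cholesterol synthesis genes included insig1, at a log2 fold change of 0.49 ± 0.19 (limma adjusted p = 0.647). The first proteasome gene by p, psmd11b, went against the list's direction, at 0.28 ± 0.13 (limma adjusted p = 0.747). Of 38 proteasome genes 32 had negative values and 6 positive. The second by p, psmb6, was at -0.33 ± 0.16 (limma adjusted p = 0.777).

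Markers of brain cell types did not pass over all genes or by camera in the full set of libraries. This held for lists of neurons (14 genes tested), glutamate (18), GABA (15) and monoamine (20) signalling, radial glia and astroglia (10), oligodendrocytes and myelin (10), microglia and leukocytes (19), vessels (12), ciliated ependyma (10), proliferation and neurogenesis (17), interferon response (10) and mitochondrially encoded genes (13). Their medians lay between -0.21 and 0.19. The synaptic gene snap25b stood at 3237 ± 423 and 3768 ± 693, and the glial gene gfap at 737 ± 349 and 495 ± 149 (limma adjusted p = 0.861 and 0.831). At an unadjusted p under 0.05 there was 1 gene each in the monoamine, microglia, vessel and proliferation lists and 0 in the others. Without control replicate 5, camera gave adjusted p of 0.0014 for glutamate and 0.0060 for GABA genes, with negative medians, and 0.0081 for oligodendrocyte and 0.0152 for proliferation genes, with positive medians. With an estimated correlation none of these 4 passed (adjusted p = 0.601 for each), nor did their scores per library (exact permutation test, adjusted p from 0.236 to 0.443). The radial glia list, with a negative median, passed camera without control replicate 6 (0.0410) or MeHg replicate 1 (0.0371). It did not pass there with an estimated correlation (adjusted p = 0.796 for each) or as a score (exact test, adjusted p = 0.729 and 0.808).

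Markers of tissues next to the brain varied strongly between libraries of both lineages. Keratin gene krt5 was 21010 in control replicate 4, 8643 in MeHg replicate 4 and 22790 in MeHg replicate 5, and at most 2056 in the other libraries. Muscle genes were highest in MeHg replicate 4, where mylpfa reached 6784. The rod opsin gene rho was 17520 in MeHg replicate 8 and at most 710 elsewhere. The retina and pineal score averaged -0.70 ± 1.57 in control libraries and 0.59 ± 2.27 in MeHg libraries (exact permutation test, two-sided p = 0.320). The MeHg mean rested largely on MeHg replicate 8, at 4.52, while the other MeHg libraries lay between -2.46 and 1.14. Scores of skeletal muscle (exact p = 0.472), epidermis (exact p = 0.989) and erythrocytes (exact p = 0.779) also differed by less than the spread. In the 7 libraries left after omitting control replicates 4 and 5 and MeHg replicates 4 and 5, 51 genes passed, 16 of them in the clock list. They shared 31 with the 44 genes of all libraries and 14 with their 18 clock genes, the other 4 being nr1d1, nr1d4b, arntl2 and bhlhe40.

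**Figure D3:**
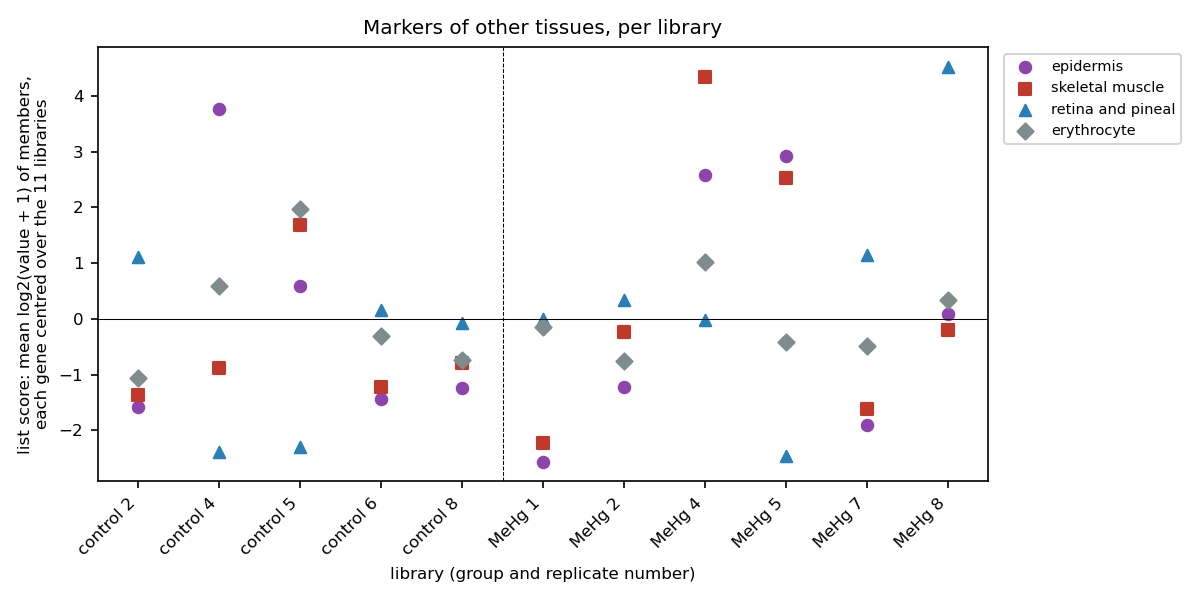
Scores of 4 marker lists of other tissues (y axis, mean log2(scaled count + 1) of list members with each gene centred over the 11 libraries) for each library (x axis), control libraries left of the dashed line. Epidermis scores reach 3.76 in control replicate 4, 2.58 in MeHg replicate 4 and 2.93 in MeHg replicate 5, and the retina and pineal score reaches 4.52 in MeHg replicate 8.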

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

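The tests of opposite clock arms, collection time, skin genes and depth were chosen after the results were seen. So was the margin of 1 SD used to read the test of genes outside the clock list.

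Within lineages, 10 of 110 groups of values held a library farther from the rest than Dixon's 95% limit, where chance gives 5.5. Numbers in parentheses are the gap to the nearest library divided by the group's range. Control replicate 5 was the lowest control for the GABA score (0.735), the epigenetic regulator score (0.741), rorcb (0.719) and per3 (0.785), and the highest control for the skeletal muscle score (0.812) and the proteasome score (0.721). MeHg replicate 4 was the lowest MeHg library for the neuron score (0.775) and the highest for the microglia and leukocyte score (0.629). MeHg replicate 8 was highest for clocka (0.626). MeHg replicate 5 was the deepest MeHg library (0.791), at 7503930 implied fragments against 4138450 for the next.

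Clock genes separated the lineages. In 100 of the 462 splits of the 11 libraries 1 split gave as many genes as the real one, the real split itself with 44 genes. The highest other gave 1, so chance assignment of libraries is argued against as the source. The splits exchange libraries between the lineages, so they cannot separate the exposure from any other difference between the lineages. With skin and muscle scores as covariates 17 of 18 clock genes stayed past the threshold, and 17 of 18 with the retina score. That is the side set beforehand as counting against RNA of other tissues. The scores differed between lineages by -0.037 for epidermis, 0.94 for muscle and 1.29 for retina. None of these lay beyond the spread between libraries (exact permutation test, p = 0.989, 0.472 and 0.320). Covariates that vary mostly within lineages can take up little of a lineage difference, so the retained genes are weak evidence. The median log2 fold change was -1.637 over 16 genes of the period (without per2), Rev-erb, Ciart, bhlhe40 and bhlhe41, and PAR bZIP groups, of which 13 were negative and nr1d4a, nr1d4b and hlfa positive, and 1.315 over 11 Bmal, Clock, npas2, nfil3 and rorc genes, of which 10 were positive. Both sets were assembled after the values of their genes were seen, so these medians describe the pattern and do not bear out a different clock phase at collection, which stays open. Whether a phase difference, if there was one, would reflect the lineage or the hour of sampling cannot be told apart, because 0 samples have a collection time in the labels, and an effect of ancestral exposure stays open and untested.

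Called genes outside the clock list, 26 in all, may simply follow the clock. Their median absolute correlation with a clock axis within lineages was 0.397. This was at percentile 78.92 of 10000 random gene sets matched on level, under the 95th percentile of 0.448. The axis was the mean of the 11 genes above minus that of the 16, sets assembled after their values were seen. Around the lineage means it ranged only from -0.44 to 0.53. The correlation lies on the side set beforehand as counting against the explanation. Its distance from the 95th percentile is less than 1 SD of the random sets (0.065), so the test does not decide. An effect of lineage that is separate from the clock cannot be told apart from clock output with these libraries.

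Some libraries held genes of other tissues. In control replicate 4 and MeHg replicates 4 and 5, picked for their high epidermis scores, 6 of 8 epidermis genes were higher than in each of the other libraries. That count restates the choice of libraries, so skin carried over at dissection was not tested by it and stays open. Low depth is argued against for MeHg replicates 4 and 5, which ranked 8 and 11 of 11 from the shallowest. Control replicate 4 ranked 3, so its rank alone does not decide. The 2 shallower libraries, control replicates 2 and 5, had epidermis scores of -1.58 and 0.59 against its 3.76. These scores argue against low depth for control replicate 4 too. No biological explanation was tested, as both lineages are represented.

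The camera call of 10 lists is not above what other groupings give. Of 100 splits, 75 gave at least as many lists as the real one, up to 19, so chance assignment cannot be excluded for that count.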

How the results depend on the processing

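Covariates, weights, library-total scaling and 2 sets of omitted libraries were chosen after seeing the data. Planned tests with DESeq2, edgeR and sva were not run. The deposited values are not raw counts, and the fragment counts implied by the step were not tried in those tests. None of the 44 genes past the threshold changed direction under the alternatives run, while 10 of 77 other genes followed changed sign in at least 1, 8 of them without scaling. Of the 44 genes, 15 stayed past the threshold in every setting run. With each library left out in turn 33 stayed, among them 16 of the 18 clock genes. The number of genes moved from 44 to 81 at an adjusted p under 0.1, 24 without scaling, 71 with voom quality weights, 129 with a residual principal component and 105 with array weights, and ranged from 36 to 72 with 1 library left out (72 without control replicate 5). Clock members ranged from 16 to 24 there, camera lists from 7 to 12, and list scores stayed at 0 to 0. Against camera's 10 lists, 0 passed with an estimated correlation, 0 by fry in one direction and 1 by fry in either direction, the clock list, which is not among the 10. The setting changed between the 2 camera runs was the inter-gene correlation, fixed at 0.01 or estimated for each list. Estimates for the 10 lists ran from 0.064 (epigenetic regulators) to 0.82 (ribosomal proteins). Fry in either direction counts changes both ways, and the clock list's members went both ways. The reason for the difference from fry in one direction was not tested. Without scaling, 12 genes were higher and 12 lower, against 16 and 28, and the median of all genes was 0.30 instead of 0.03. There the size factors were undone and depth was left uncorrected. A call lost in that setting therefore does not show that a gene fails under another scaling.

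The replicate number as a block, over the 8 libraries with shared numbers, gave 20 genes and 9 clock members, and the same 8 libraries without a block 23 and 11, so fewer libraries account for most of the drop. The clock genes arntl1a, arntl2, clocka, cry1a, per3, nr1d1 and bhlhe40 passed in neither fit. With the block per1a and ciarta did not pass either (limma adjusted p = 0.0652 and 0.0558). Residuals of same-numbered libraries correlated at 0.099, 0.463, 0.193 and 0.055, so the numbers were not taken as pairs, and not every library correlated best with its own number. A block for list scores was not run, since so few pairs cannot reach the threshold. Among values of single genes, 3994 kept their side of the threshold, 199 fell below it and 13 rose past it, the latter hspe1, hsp90aa1.2 and npas4a. Depth limits low genes most, as for fbxl3l, whose control libraries held 0 to 3 fragments each.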

Other observations

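The gene pairs and the light gene set were chosen after the values were seen. Related clock genes moved alike in some pairs and apart in others, and differences within pairs were not tested. Both per1a and per1b fell, and both arntl1a and arntl2 rose. The cryptochrome gene cry1a fell from 1286 ± 228 in control brains (SD, n = 5) to 631 ± 84.0 in MeHg-lineage brains (SD, n = 6; limma adjusted p = 0.0046), while cry2b rose. Beside nr1d2b, which fell, nr1d2a had a log2 fold change of -0.14 ± 0.44 (SE, limma adjusted p = 0.959), and beside nfil3-5, which rose, nfil3-6 had -0.67 ± 0.32 (SE, limma adjusted p = 0.777). The bZIP activator gene tefa fell from 1925 ± 368 to 622 ± 46.7, and the repressor gene bhlhe41 from 1019 ± 245 to 254 ± 56.8 (limma adjusted p = 6.3e-05 and 0.00017). Without scaling between libraries, cry1a and tefa did not pass, at log2 fold changes of -0.73 ± 0.40 and -1.32 ± 0.40 (SE), nor did arntl1a, and without MeHg replicate 7 arntl2 did not.

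A set of 9 genes known to respond to light or to act in repair of light damage, assembled from textbook knowledge with the values of several members already known and so no independent evidence of its direction, had negative changes in 9 of 9, with a median of -1.02 and 5 past the threshold, namely cry1a, cry5, cry-dash, ddb2 and tefa. Without scaling the median was -0.73 and 3 passed. Others such as xpc and neil1 had values of -0.52 ± 0.27 and -0.60 ± 0.23 (limma adjusted p = 0.810 and 0.640). The set is not separate from the clock list, to which its members per2, cry1a, cry5 and tefa also belong.

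The gene oaz1a, chosen after its values were seen, is listed at 0 in control replicate 4, while control replicates 2, 5, 6 and 8 stood at 2.29, 4941, 1688 and 32.3 scaled counts and the 6 MeHg-lineage libraries between 1661 and 3662. It did not pass the threshold (limma adjusted p = 0.616). Such gaps were not confined to control libraries. The gene ctsba, with a median of 468, stood at 9.14 in control replicate 2, 0 in control replicate 5 and 1.48 in MeHg replicate 2. The gene si:ch211-213a13.11, with a median of 246, stood at 2.29 and 0 in control replicates 2 and 8. It stood at 8.60 and 3.63 in MeHg replicates 7 and 8.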
